A study of Mus musculus with 10 samples.

How the data were processed

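RNA from the lateral and septal walls of the mouse left ventricle was compared on 10 two-colour arrays, 2 for each of 4 dyssynchronous hearts and 2 for 1 control pool of synchronous mice. Per the submitters' processing notes the arrays were read with Agilent Feature Extraction 7.5. The deposited values were taken as the log10 ratio of Cy5 over Cy3, since they are signed, have a median of 0 on every array and come from software whose usual output is that ratio, but the labels state neither the log base nor the direction. As deposited, the ratios of Myl7, Ecrg4, Dkk3 and Comp change sign when the dye labels are exchanged. The values were therefore taken as not already turned to 1 wall over the other, which rests on few genes. Across genes the 2 arrays as deposited correlated at 0.30, 0.35, 0.28 and 0.17 in hearts 1, 3, 4 and 5, and at 0.30 in the pool. By the check fixed beforehand, a correlation above 0 would mean values already turned. In that case the wall and dye effects given here would be exchanged. The dye normalization and any filter behind the deposited ratios are not given in the sources used here, and which of scale, centring and direction the authors set is therefore not known beyond the median of 0. Values of -2, found only for features without a gene name, were taken as no value. Exact zeros made up 7.69% to 15.1% of features per array, and their meaning is not stated. Channel intensities were not analysed here, so dim features could not be left out.

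Values were multiplied by 3.32 to the log2 scale and signed by the dye labels so that positive values are higher in the lateral wall. Of 22393 features, 18218 had 1 gene symbol, 16 had several and 4159 had none, and 18175 Entrez numbers were found in the gene table with 0 differing symbols. Features of a gene were averaged, which left 16504 genes, all with a value on all 10 arrays. The spread of the log2 ratios on an array, as the median absolute deviation, was 0.22 to 0.50. The number of arrays limits the precision of every value.

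The 2 arrays of a heart were averaged and the 4 hearts and the pool were fitted together in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with eBayes moderation. The first test set the mean of the 4 hearts against 0, and the second set the dyssynchronous hearts against the pool, which as a single replicate is assumed to vary like 1 heart. Genes passed at a Benjamini-Hochberg adjusted p under 0.05, and all tests were two-sided. Genes beyond 1.5-fold in one direction in every heart were counted without a test. For the 42 gene lists, camera with a preset correlation of 0.01 was run beside camera with an estimated correlation and fry, each adjusted over the lists. Correlations between hearts were computed across genes as values only.

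The rule for named genes, the gene lists and the tests were fixed before the data were examined. As no gene passed, the named genes are, for each test, the 8 highest and 8 lowest by moderated statistic with the same sign in all 4 hearts, which in the second test is the sign of the difference from the pool. To these were added up to 4 genes per list with the smallest p in the first test, a fixed set of cardiac genes where measured, and the 8 highest and 8 lowest genes of the pool among those beyond 1.5-fold in one direction on both of its arrays. The genes beyond 1.5-fold in all hearts and those called by the fit with a dye term are outside that rule and were named after their values were seen.

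The alternatives tried were subtraction of array medians, a common spread between arrays, fits of single arrays with the heart as a block (limma duplicateCorrelation) with and without a dye term, each dye orientation alone, filters on dye bias, exact zeros and missing values, single probes, robust and unmoderated tests, the 4 hearts alone, a turned sign of the pool, other fold limits and each heart left out. The procedure was tested on simulated data with 16504 genes and 50 genes at each fold. For lateral against septal wall, limma on averaged dye swaps called 34%, 58%, 94% and 100% of genes simulated at 1.5-fold, 2-fold, 4-fold and 8-fold, with 5 of 16304 unchanged genes called. For the difference from the pool it called 0%, 2%, 62% and 78%. The simulated spreads between hearts were moderated ones, which differ less between genes than the measured spreads. In the data Myl7, 23.3-fold higher in the septal samples, did not pass limma on averaged dye swaps (adjusted p 0.732). The simulated shares may therefore be too high, and 0 calls in the data do not show that 4-fold differences are absent. The count of genes beyond 1.5-fold in all 4 hearts took in 8%, 76%, 100% and 100% of them and 7 unchanged genes with moderated spreads, or 8 with unmoderated spreads. A simulated shift of 0.30 in a list of 27 genes was called by camera with the preset correlation and by fry, and not with the estimated correlation. The simulated genes varied independently, so this cannot show which method is sound for lists whose genes are correlated. The shift was also larger than the median of every list called in the data, the farthest from 0 being -0.21 for atrial cardiomyocyte markers. No paired analysis between the groups was possible because the single control pool shares no animals with the dyssynchronous hearts. Features without a single gene name were left out of the gene tests and are treated apart.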

Results

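The data came from mouse left ventricles in which the lateral wall and the septal wall were compared directly, with RNA of both walls of a heart labelled with Cy3 and Cy5 on 1 array. There were 4 dyssynchronous hearts, numbered 1, 3, 4 and 5 in the labels, and 1 control pool of RNA from synchronous mice. Dyssynchrony, a loss of coordinated contraction between the walls, is tied in the study's design to an implanted pacemaker. Each heart and the pool had 2 arrays with the dyes exchanged, which gives 10 arrays of 10 RNA samples. Values below are log2 ratios of lateral over septal wall, averaged over both dye orientations, so a positive value is higher laterally and a negative value is higher in the septum. The direction and the scale are likely rather than stated, as set out with the processing. Each array had 22393 features, which gave 16504 named genes with values on all 10 arrays. The number of arrays limits the precision, and the control pool has no replicate.

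The first comparison asked which genes differ between the walls of a dyssynchronous heart and do so in every animal. Myl7, the atrial myosin regulatory light chain, had the lowest mean ratio of the genes found in all hearts, at -4.54 ± 1.32 (SD, n = 4 hearts), or 23.3-fold higher in the septal samples, against -0.12 in the control pool. Myl4, the atrial essential light chain, stood at -2.14 ± 1.496 (pool -0.47) and Myh7, the slow beta-myosin heavy chain, at -1.46 ± 0.87 (pool -0.82). Genes of secreted proteins in this set included Dkk3, a Dickkopf family protein, at -2.71 ± 1.13 (pool -0.59), and Ecrg4, which encodes a secreted peptide precursor, at -2.70 ± 0.54 (pool -0.29). Comp, a cartilage and tendon matrix protein, was at -2.46 ± 1.20 (pool -0.52).

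In all, 18 genes lay beyond 1.5-fold in the same direction in all 4 hearts, 14 of them higher in the septal wall and 4 higher in the lateral wall. Simulations gave 7 or 8 unchanged genes by the same rule. With the signs of single hearts turned, the highest other count was lower than that, at 4, though 8 sign patterns are too few for a test. The other septal genes were Angptl7, an angiopoietin-like secreted protein (-1.82 ± 0.63), the Iroquois transcription factor Irx2 (-1.21 ± 0.30), the glucagon receptor Gcgr (-0.98 ± 0.52), the cartilage protein Ucma (-0.97 ± 0.22), 8430432A02Rik (-0.88 ± 0.16), Armcx4 (-0.77 ± 0.11), the thyroxine-activating deiodinase Dio2 (-0.74 ± 0.07) and the homeobox gene Alx1 (-0.69 ± 0.09). The lateral genes were Olfr1463, an odorant receptor gene (1.16 ± 0.42), the sodium-hydrogen exchanger Slc9a2 (0.99 ± 0.49), the vomeronasal receptor gene Vmn1r8 (0.89 ± 0.25) and Cnn1, the smooth muscle protein calponin (0.85 ± 0.26). The direction held on all 8 arrays of the hearts for 15 of the 18 genes, and for Alx1 on only 4 arrays. The control pool, as the mean of its 2 arrays, was beyond 1.5-fold in the same direction for 6 of the 18, namely Dkk3, Myh7, Irx2, Gcgr, Cnn1 and Olfr1463. On both pool arrays this held only for Myh7, Irx2 and Cnn1, and Olfr1463 had an exact 0 on 1 of them. Dkk3 passed the limit narrowly, while Slc9a2 (pool 0.565) and Vmn1r8 (pool 0.577) fell just short. A further comparison, chosen after the data were seen, found 5 genes whose 4 hearts all also lay at least 1.5-fold from the pool: Myl7, Ecrg4, Angptl7, Ucma and 8430432A02Rik, all on the septal side. With 1 heart left out the remaining hearts shared more genes, 36 without heart 1, 41 without heart 3, 31 without heart 4 and 35 without heart 5.

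**Figure D1:**
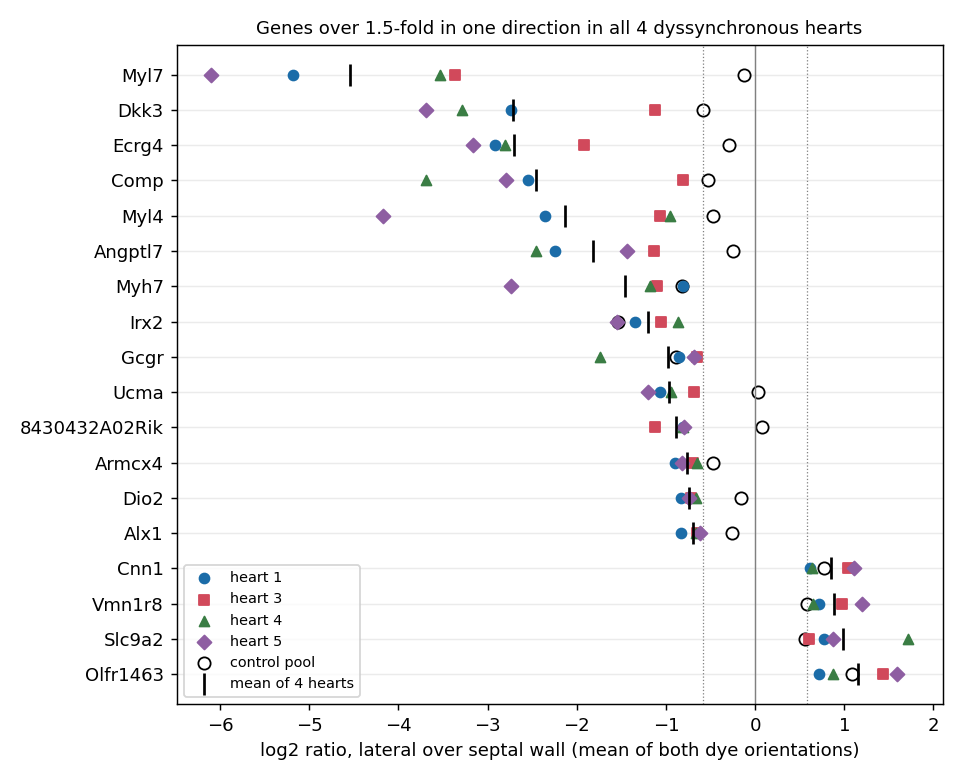
Log2 ratio of lateral over septal wall (horizontal axis) for the 18 genes beyond 1.5-fold in one direction in all 4 dyssynchronous hearts. Filled symbols are single hearts, each the mean of both dye orientations, open circles are the control pool, short bars are means of 4 hearts and dotted lines mark 1.5-fold; Myl7 lies farthest from 0 in the hearts, with a mean of -4.54 against -0.12 in the pool.

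No gene passed the test across all 16504 genes. limma with the dye swaps of each heart averaged called 0 genes at an adjusted p under 0.05, with 934 genes at an unadjusted p under 0.05 where 825.2 are expected by chance, and an ordinary test without moderation also called 0. For Myl7 the adjusted p was 0.732, with a septal ratio in 4 of 4 hearts, and for Ecrg4 it was 0.643, also in 4 of 4. An exact sign-flip permutation test of 4 hearts cannot give a two-sided p below 0.125. A limma fit of all arrays with a dye term and the heart as a block called 20 genes, each with the same sign in all 4 hearts. That fit counts the 2 arrays of a heart as nearly independent and so overstates the number of replicates. Of these, 6 were higher in the lateral wall: Stk39, a kinase that regulates ion cotransporters (0.54 ± 0.05, adjusted p 0.00612), Lrtm1 (0.77 ± 0.18), the neuropeptide gene Nmb (0.71 ± 0.20), Cnn1, the chemokine Cxcl14 (0.52 ± 0.09) and the noncoding RNA Neat1 (0.50 ± 0.15). The 14 higher in the septal wall were Myl7 (adjusted p 0.00686), Ecrg4 (adjusted p 0.00612), Dkk3, Angptl7, Irx2, Ucma, Armcx4, 8430432A02Rik, Fibin (-1.08 ± 0.43), the myosin-binding protein Mybpc2 (-0.84 ± 0.27), the matrix protein Cilp (-0.74 ± 0.24), the stretch-responsive muscle genes Ankrd1 (-0.67 ± 0.24) and Ankrd23 (-0.50 ± 0.18), and the Z-disc protein Myot (-0.59 ± 0.15). Among the 20 genes, 9 were also in the set beyond 1.5-fold in all hearts. Several genes outside that set had ratios of the same direction in the control pool. Pool ratios were 0.40 for Stk39, 0.28 for Lrtm1, 0.77 for Nmb and 0.28 for Cxcl14. They were -0.51 for Ankrd1, -0.24 for Myot and -0.42 for Mybpc2, while Cilp was at 0.30.

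Genes of calcium handling and conduction showed smaller ratios, and none passed over all genes. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was at -0.08 ± 0.10, its inhibitor Pln at 0.02 ± 0.01, the calcium release channel Ryr2 at 0.20 ± 0.24, the sodium-calcium exchanger Slc8a1 at -0.06 ± 0.07 and the calcium channel Cacna1c at -0.18 ± 0.15. The gap junction gene Gja1 was at 0.18 ± 0.21 in the hearts and -0.33 in the pool, with 3 of 4 hearts higher laterally (adjusted p 0.797). Gja5 was at 0.15 ± 0.22. Among channel genes, Kcnd2, of the transient outward potassium current, was at 0.55 ± 0.27 (pool 0.51), Kcnip2, its auxiliary subunit, at 0.16 ± 0.52, Kcnq1 at -0.11 ± 0.15, and the pacemaker channels Hcn2 and Hcn4 at 0.01 ± 0.12 and -0.46 ± 0.40. Of 19 measured genes in the conduction system list, 3 passed when adjusted over the list alone, all toward the septal side, against 0 over all genes: Cacna1g, a T-type calcium channel (-0.63 ± 0.28), the potassium channel subunit Kcne1 (-0.55 ± 0.27, pool -0.56) and Pcp4, a calmodulin-binding protein (-0.39 ± 0.13, pool -0.84). Among stress and load markers, Nppa, the atrial natriuretic peptide, was at -1.35, 0.20, -0.08 and -2.27 in hearts 1, 3, 4 and 5, Nppb at -0.23 ± 0.17, Acta1 at -0.08 ± 0.18 and the cytokine Tnf at -0.09 ± 0.80. The matrix genes Postn, Col1a1 and Col3a1 stood at -0.39 ± 0.30, -0.50 ± 0.66 and 0.18 ± 0.17. On the arrays with lateral RNA in Cy5 alone the Col1a1 ratio was 0.13, and with lateral RNA in Cy3 alone the Pln ratio was -0.15 and the Cacna1c ratio 0.16.

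Of 42 gene lists fixed before the data were examined, 9 passed camera with a preset correlation, 4 toward the lateral and 5 toward the septal wall, and 0 passed camera with an estimated correlation or fry (15, 1 and 9 lists at an unadjusted p under 0.05). Smooth muscle and pericyte markers were higher laterally, with a median of 0.14 (pool 0.11) and an adjusted p of 7.26e-05, but an adjusted p of 0.579 with an estimated correlation. Of its 20 genes, 9 were higher laterally in all 4 hearts, and 2 passed when adjusted over the list alone, Cnn1 and the actin filament protein Lmod1 (1.00 ± 0.43, pool 1.06). The hypertrophy and fetal gene program was lower laterally (median -0.15, pool -0.06, adjusted p 5.93e-04, and adjusted p 0.579 with an estimated correlation), with Myl7 and Ankrd1 passing when adjusted over the list alone. Atrial cardiomyocyte markers had a median of -0.21 (pool -0.0027, adjusted p 0.00385, and adjusted p 0.579 with an estimated correlation), with Myl7, Dkk3 and the growth factor homologue Fgf12 (-0.37 ± 0.17) passing when adjusted over the list alone. Within that list the atrial transcript Nppa was beyond 1.5-fold on the septal side in hearts 1 and 5, where Myl7 (-5.18 and -6.10) and Myl4 (-2.35 and -4.17) were also lowest, while Sln, with exact zeros on 5 of 10 arrays, was so in neither. Without the genes shared by all hearts, an alternative chosen after the data were seen, the atrial median was -0.10 (adjusted p 0.143).

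Matricellular genes and TGF-beta targets were lower laterally (median -0.15, pool -0.09, adjusted p 0.00747, and adjusted p 0.579 with an estimated correlation), with Comp, Cilp and Ccn4 (-0.73 ± 0.31) passing when adjusted over the list alone. On the Cy5-lateral arrays alone the Ccn4 ratio was 0.07. Sarcomere genes had a median of -0.07 (pool -0.12, adjusted p 0.01001, and adjusted p 0.586 with an estimated correlation), and Myot passed when adjusted over the list alone. Skeletal muscle markers had a median of -0.20 (pool -0.0052, adjusted p 0.00767, and adjusted p 0.579 with an estimated correlation), with Myot and Mybpc2 passing when adjusted over the list alone. Heart 5 carried this shift, with a median of -0.70 in heart 5 and 0.03 (adjusted p 0.742) without it. Macrophage and monocyte markers (median 0.12, pool 0.07, adjusted p 0.0034), oxidative phosphorylation genes (median 0.04, pool 0.0070, adjusted p 0.00767) and inflammation genes (median 0.05, pool 0.05, adjusted p 0.0277) were higher laterally, each with an adjusted p of 0.579 with an estimated correlation. Of the 44 oxidative phosphorylation genes, 16 were higher laterally in all 4 hearts, such as the complex I subunit Ndufv2 (0.16 ± 0.09). Cxcl14 was the inflammation gene that passed when adjusted over the list alone. Leaving out a heart ended the call for sarcomere genes (adjusted p 0.085 without heart 3 and 0.106 without heart 5), matricellular genes (0.0685 without heart 4), inflammation genes (0.213 without heart 3) and macrophage markers (0.0715 without heart 3). Change in either direction, which fry tests with its mixed p, passed for 14 of the 42 lists.

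**Figure D2:**
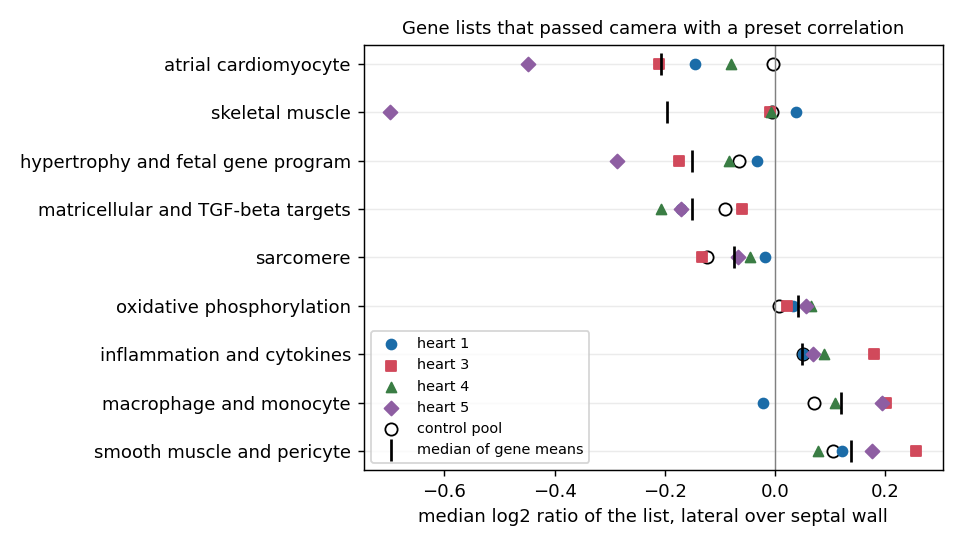
Median log2 ratio of lateral over septal wall (horizontal axis) in each of the 9 gene lists that passed camera with a preset correlation, of which 0 passed with an estimated correlation. Filled symbols are medians of single hearts, open circles the control pool and short bars the medians of the gene means over 4 hearts; for skeletal muscle markers heart 5 stands apart at -0.70.

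The second comparison asked which wall ratios in dyssynchronous hearts depart from those of synchronous animals. Myl7 lay -4.42 from the pool (adjusted p 0.956) and Ecrg4 -2.41 (adjusted p 0.850), in each case with 4 of 4 hearts below the pool, and neither passed. The 16 genes with the highest and lowest moderated statistics had mean ratios between -0.14 and 0.12 in the hearts, with Morc2b at -0.41 in heart 1 the farthest single value from 0, and a larger ratio in the pool. Of these, 7 had exact zeros, whose meaning is not stated, on 4 to 8 of the 10 arrays. Cnnm2, a magnesium transport gene, was at -0.01 ± 0.07 in the hearts (n = 4) and 1.87 in the pool, Slc49a4 at 0.08 ± 0.10 against 1.84, Dtnb, a dystrobrevin, at 0.02 ± 0.19 against 2.16, and Lrrtm3, a synaptic adhesion gene, at 0.02 ± 0.13 against 1.71. In the other direction Bet1, of vesicle transport, was at -0.04 ± 0.11 against -1.40 and Nelfe, of transcription elongation control, at -0.03 ± 0.11 against -1.15. The other named genes were Morc2b, Pop1, Pcdhb15 and Krt14, lower than the pool, and Slco1a1, Adgrf1, Speer4f1, Slc22a19, Tnfrsf26 and Msh3, higher than the pool. Only 2 of these 16 genes, Slc49a4 and Pop1, were beyond 1.5-fold in one direction on both arrays of the pool.

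limma with averaged dye swaps called 0 genes for this difference, with 783 at an unadjusted p under 0.05 (825.2 expected) and a lowest adjusted p of 0.644, under the assumption that the pool varies like 1 heart. The fit of all arrays with a dye term called 3, all lower than the pool in 4 of 4 hearts: Slc49a4 (difference -1.76, adjusted p 0.0077), Pop1, an RNase P component (-1.39, adjusted p 0.0131), and the odorant receptor gene Olfr507 (-1.74, adjusted p 0.0390). An ordinary test without moderation called 1, Agr3, named here after its values were seen, which was at exactly 0 in 3 of the 4 hearts and at -0.49 in the pool (difference 0.49, adjusted p 0.00677). Camera called 0 of 42 lists (6 at an unadjusted p under 0.05), as did camera with an estimated correlation and fry. The mixed p of fry passed for 3, the epicardial, regional patterning and endocardial lists. The epicardial list was expected to be higher laterally because the septum lacks epicardium. In the first comparison, of lateral against septal wall, it had a median of -0.08 (camera adjusted p 0.132, and adjusted p 0.579 with an estimated correlation). Its median was below 0 in all 4 hearts, with 5 of 22 genes lower laterally in every heart and 0 higher, so it leans against the direction taken here without passing. If the direction were turned, every lateral and septal side given here would be exchanged. In the comparison with the pool 1 of its 22 genes, Krt14, passed when adjusted over the list alone.

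In the control pool by itself, 194 genes were beyond 1.5-fold in one direction on both arrays, 99 higher laterally and 95 higher in the septum. Among these 194, besides Slc49a4, Pop1 and Olfr507, the highest were Olfr667 (2.14), Sncg, a synuclein (1.69), Naip6, an inflammasome sensor (1.64), Sgpp1 (1.62) and Tmem247 (1.52). The lowest were Olfr1208 (-1.62), Irx2 (-1.53), Slc44a3 (-1.49), Mri1 (-1.44), Tkfc (-1.43), the receptor Ror1 (-1.42), Olfr1258 (-1.40) and Slc35d3 (-1.36). Of the 194, 3 were beyond 1.5-fold the same way in all 4 dyssynchronous hearts (Irx2, Myh7 and Cnn1). Irx2 had similar ratios in both settings, -1.21 ± 0.30 (SD, n = 4) and -1.53.

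The third comparison asked how far wall differences are shared between animals. Across 16504 genes, which are not independent replicates, the correlation between 2 hearts was between -0.006 and 0.079 with a median of 0.071 over 6 pairs, and between a heart and the pool it was 0.032 to 0.079. Dye effects were larger than wall effects, provided that the deposited values had not already been turned. The SD over genes was 0.34 for the mean dye effect and 0.20 for the mean wall effect, and 1552 genes against 220 exceeded 1.5-fold. The 2 arrays of a heart, once turned to lateral over septal, correlated at -0.30, -0.35, -0.28 and -0.17 in hearts 1, 3, 4 and 5. When hearts were compared only through arrays of opposite orientation the median correlation was -0.17, and through arrays of equal orientation it was 0.23, each over 12 array pairs. The large septal ratios of Myl7, Ecrg4, Dkk3 and Comp had the same sign in both orientations.

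**Figure D3:**
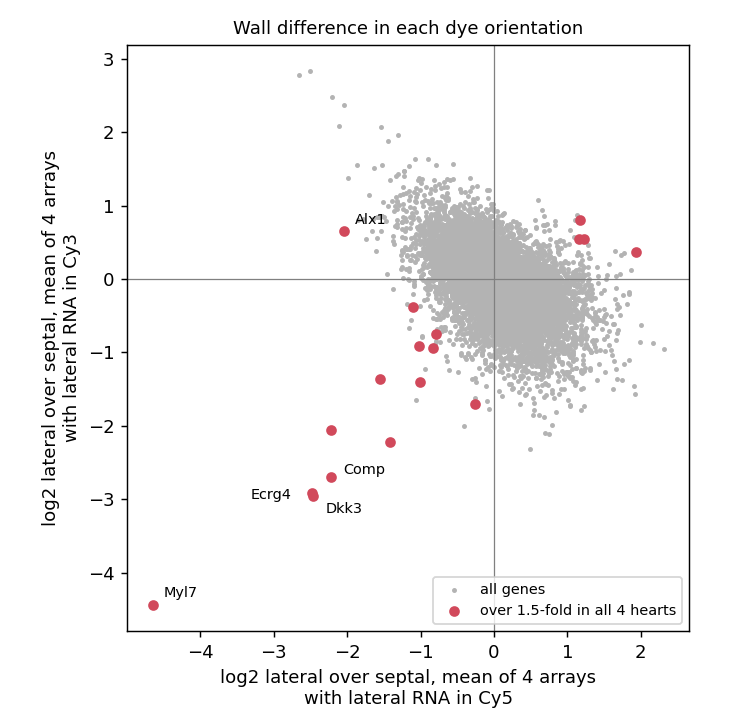
Mean log2 ratio of lateral over septal wall for each gene on the 4 arrays with lateral RNA in Cy5 (horizontal axis) and the 4 arrays with lateral RNA in Cy3 (vertical axis) of the dyssynchronous hearts. Grey points are all 16504 genes, whose orientations correlate at -0.48, and red points the 18 genes beyond 1.5-fold in all 4 hearts, most of which have the same sign on both axes, unlike Alx1.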

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

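The tests of dye bias, of atrial muscle, of the control pool's single arrays and of the sign patterns below were chosen only after the result was seen, while those with the added marker lists were fixed before those lists were measured. A sample far from the others is found by chance in about 1 in 20 sets of 4 hearts. Here 101 sets were examined and 4 had such a heart, where 5.05 are expected.

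The ratio of 8430432A02Rik was -1.12 in heart 3 and between -0.81 and -0.79 in the others. Nrn1, which encodes a neurite growth protein, was at 0.78 in heart 4 and between 0.56 and 0.58 in the others. Fibin, a secreted protein gene, was at -0.44 in heart 3 and between -1.37 and -1.22 in the others. Among features without a single gene name, outside the main measurement, 3 of 3746 were beyond 1.5-fold in the same direction in all 4 hearts and farther from 0 than the pool, with means of -0.80 ± 0.15, 1.505 ± 0.49 and -1.29 ± 0.32 (SD, n = 4).

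The median of the skeletal muscle markers was -0.70 in heart 5 and between -0.01 and 0.04 in the others. In heart 5, 11 of the 18 markers were beyond 1.5-fold on the septal side, 10 of them with that direction on both arrays, among them Myh4 (-2.96), Mylpf (-1.48), Tnnt3 (-1.34), Tnni2 (-1.24) and Pvalb (-1.14), and 2 markers were so in the pool. Skeletal muscle tissue in that septal sample is a candidate source, but an added list of 14 further measured skeletal muscle genes had a median of -0.04 in heart 5, at percentile 22.4 of 10000 random lists, and Ckm, which heart muscle also expresses, was at 0.19. The added list lies neither low nor high enough to decide, and skeletal muscle and a change in the heart itself cannot be told apart. No biological explanation was tested, since the labels give no trait that sets heart 5 apart.

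The 14 genes beyond 1.5-fold on the septal side in all 4 hearts, led by Myl7, Dkk3, Ecrg4 and Comp, were weighed against 3 explanations, with sides that would be exchanged if the direction of the ratios were turned. For dye bias of the probes, 12 of the 14 had the septal direction on all 8 arrays, the exceptions being Dio2 with 7 and Alx1 with 4. The genes had been chosen on the mean of both dye orientations, in which an equal and opposite dye effect cancels. Such an effect alone therefore cannot place a gene in the set, provided that the deposited values had not already been turned. Agreement between orientations was favoured by the choice and adds no separate support. A dye effect of unequal size in the 2 orientations was not decided. Atrial muscle in the septal samples may contribute and stays open: 0 hearts had both Nppa and Sln beyond 1.5-fold on the septal side, but 5 of the 10 Sln values were exact zeros, Nppa was so in hearts 1 and 5 (-1.35 and -2.27), where Myl7 and Myl4 were lowest, and the atrial list without the shared genes lay at percentile 1.38 of 10000 random lists for the mean, and at 41.5, 16.1, 87.8 and 0.01 in hearts 1, 3, 4 and 5. Cartilage, tendon or valve tissue also stays open: an added list of 14 measured matrix genes had a median of -0.07, at percentile 3.38 of 10000 random lists. However, its medians were 0.09, 0.03, -0.08 and 0.01 in hearts 1, 3, 4 and 5. The matrix list's median was lower still in the pool, at -0.14 and percentile 1.25, although most of the 14 septal genes had smaller ratios there than in the hearts. An effect of dyssynchrony, which the design names, remains untested against these, and for the count of 18 genes the 8 sign patterns of the hearts are too few for a share under 0.05, with 18 in the real pattern and 4 in the highest other, while in simulations 7 or 8 unchanged genes met the same rule.

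The 16 genes with the highest and lowest moderated statistics against the pool had mean ratios between -0.14 and 0.12 in the hearts, and only 2 of the 16 were beyond 1.5-fold in one direction on both arrays of the pool. One array of the control pool is a candidate source of part of these differences, the more extreme array being the one with lateral RNA in Cy5 except for Bet1 and Nelfe. For 6 of the 16 the other array held an exact 0 of unknown meaning, and of the other 10, 3 had opposite signs on the pool's arrays and 5 the same sign with the smaller ratio within 1.5-fold, narrowly so for Morc2b (0.55), Nelfe (-0.54) and Pcdhb15 (0.53). A difference between dyssynchronous and synchronous hearts was not tested apart from this, because the pool has no replicate.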

How the results depend on the processing

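The alternatives with features lacking a gene name, with a distance from the pool and with lists without the shared genes were chosen after seeing the data. For the wall difference, limma on single arrays called 23 genes with the heart as a block and 20 with a dye term, 19 in both, and every other setting called 0. The block correlation was -0.05 with the dye term and -0.28 without it. At such values both fits treat the 2 arrays of a heart much as separate replicates, and so overstate the number of replicates. Whether this alone gave the calls was not tested. For the difference from the pool the same fits called 3 and 3, the unmoderated test 1 (Agr3, at exactly 0 in 3 hearts), and 171 genes had 4 hearts on one side of both control arrays and over 1.5-fold from the mean of these arrays. Without the fold limit the share was 11.8%, and the 13.3% that chance gives for exchangeable values is no valid reference, since the controls here are single arrays of opposite orientation. The count of 18 shared genes was 4 at 2-fold (Myl7, Dkk3, Ecrg4 and Angptl7), 52 at 1.3-fold, 7 on all 8 arrays, 3 for features without a single gene name and 5 with the distance from the pool. It ranged from 31 to 41 with a heart left out, as fewer hearts had to share a gene. The 9 lists fell to 0 with an estimated correlation and 0 with fry (the cause was not tested), and numbered 9 to 11 with a heart left out and 8 without the shared genes. For oxidative phosphorylation and inflammation genes the estimated correlations, 0.0086 and 0.0073, lay below the preset 0.01. A higher correlation between genes therefore does not explain the rise in p for these lists. The skeletal muscle median ranged from -0.26 to 0.033 with a heart left out, the latter, turned, without heart 5. The median correlation between hearts turned to -0.17 for arrays of opposite orientation, where dye effects enter with opposite sign.

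Turned wall ratios were sought only among named genes with the same sign in all 4 hearts. With lateral RNA in Cy3 only, ratios turned for Alx1 (0.65), Atat1 (0.16), Pln (-0.15) and Cacna1c (0.16), and the differences from the pool for Dtnb (0.26) and Morc2b (0.091). With lateral RNA in Cy5 only, they turned for Col1a1 (0.13), Ccn4 (0.070), Sftpa1 (0.12) and, against the pool, Bet1 (-0.12). The cause was not tested. Turning the sign of the pool turned all 16 named differences by construction: Adgrf1 -0.99, Slco1a1 -1.08, Bet1 -1.43, Tnfrsf26 -0.85, Speer4f1 -0.90, Nelfe -1.18, Slc22a19 -0.81, Msh3 -0.75, Cnnm2 1.86, Slc49a4 1.92, Lrrtm3 1.73, Dtnb 2.18, Krt14 1.01, Morc2b 1.93, Pcdhb15 1.36 and Pop1 1.53. Of the 932 alternative values of named wall ratios, 880 counted as unchanged, 39 passed the threshold, 7 turned and 6 moved. For genes with the same sign in all 4 hearts, unchanged means the same direction without passing. For the other genes it means a shift smaller than the SD of the hearts without passing, so a change of direction was not counted. Of 247 differences from the pool, 224 kept direction and side of the threshold, 4 passed it, 19 turned and 0 moved. Median subtraction and the filter on missing values moved nothing, since all medians are 0 and all genes have values. Signal over background could not be assessed from ratios alone.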

Other observations

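Several groups outside the comparisons above had members with the same direction in all 4 hearts, none passing over all genes with limma on averaged dye swaps. With random signs a share of 0.125 of genes would have such agreement, so it marks no pattern by itself. Potassium channel genes did not shift as a list (median 0.04, adjusted p 0.861, and adjusted p 0.942 with an estimated correlation), yet fry's mixed p, which reads change in either direction, had an adjusted value of 0.00597. Of the 24 measured potassium channel genes, 2 were higher laterally and 2 higher in the septum in all 4 hearts. Kcnd2 (0.55 ± 0.27) and Kcnj8, of an ATP-sensitive channel (0.23 ± 0.11), were higher laterally and Kcne1 (-0.55 ± 0.27) was higher in the septum, each in 4 of 4 hearts (SD, n = 4). Oxidative stress genes had 8 of 27 members higher laterally in all hearts. Among them were the metallothioneins Mt2 (0.30 ± 0.09, pool 0.28) and Mt1 (0.12 ± 0.03, pool 0.03). The list had a median of -0.01 and a mean of -0.02, although camera gave the lateral direction (adjusted p 0.817, and adjusted p 0.942 with an estimated correlation).

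Stretch and immediate early genes had a median of -0.06 (adjusted p 0.0889, and adjusted p 0.579 with an estimated correlation), with Hbegf, an EGF family growth factor (-0.26 ± 0.09), and the antiproliferative gene Btg2 (-0.21 ± 0.04, pool 0.18) higher in the septum in 4 of 4 hearts. Vascular endothelial markers had a median of 0.08 (adjusted p 0.0929, and adjusted p 0.579 with an estimated correlation), with Egfl7 (0.21 ± 0.14) and the fatty acid carrier Fabp4 (0.16 ± 0.09) higher laterally in 4 of 4 hearts. Mstn, which encodes the muscle growth inhibitor myostatin, was at -0.34 ± 0.10 (pool -0.11). The lung and thymus list did not pass, with a median of -0.10 (adjusted p 0.330, and adjusted p 0.772 with an estimated correlation), with 1 gene, Sftpa1 (-0.36 ± 0.13), passing when adjusted over the list alone, although its ratio was 0.12 on the arrays with lateral RNA in Cy5 alone.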
